A study of Mus musculus with 9 samples.

How the data were processed

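Ovaries of adult mice were collected 40 h after injection of pregnant mare serum gonadotropin (PMSG), and total RNA was sequenced in 9 libraries, 3 from each of 3 genotypes. The genotypes were wild type (WT), the double knockout of the liver X receptors (DKO) and the double knockout labelled as carrying a transgene named for the Amh gene and LXRb (DKO_TG). Groups and replicate numbers were taken from the sample labels. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

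The authors deposited 1 table of RPKM values (reads per kilobase of transcript, scaled by the reads of the library) for 54838 genes, with 1 column for each library. Per the submitters' processing notes, the tools named were cutadapt, HISAT2 2.1.0, HTSeq 0.5.4p5 and DESeq2 1.2.8, and the genome build was mm10. The step that made the RPKM values, the annotation and the use of strand in counting are not given in the sources used here. Gene identifiers were matched to the mouse annotation GENCODE M21 on mm10 for 54723 genes, which gave symbols, coordinates, gene classes, exon lengths and GC content. The 3 columns of the transgene-labelled libraries spell the transgene differently from the sample titles and were matched by group and number.

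RPKM values do not give the number of reads behind them directly. Multiplying each value by the union of exon lengths gave whole numbers of reads for 97.8% of the values above 0, within 0.01 read or a relative difference of 1e-06, and whole reads in all libraries for 53992 genes. The recovered totals were between 40.1 M reads (DKO_TG replicate 2) and 59.4 M reads (DKO replicate 3). The library size behind each RPKM value was not the plain total of reads. Its ratio to the total was 0.793 to 0.920 in the WT libraries and 1.03 to 1.11 in the others, so the deposited values carry a rescaling between libraries. All 37 genes named mt- were listed at 0 in every library, so mitochondrially encoded RNA could not be compared.

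Because RPKM values are not counts, differences were tested on log2(RPKM + 0.5) with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3. All 9 libraries entered one fit, so the genotypes share 1 estimate of the spread. Genes with an RPKM of at least 0.5 in at least 3 libraries were tested (18889 genes). A gene was called when the Benjamini-Hochberg adjusted p was under 0.05. Fold changes are on the log2(RPKM + 0.5) scale and understate the change of weakly expressed genes. A test on counts had been planned for the case of a count table; it was replaced because the table holds RPKM.

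Before the data were examined, 25 gene lists were fixed for pathways and cell types of the ovary and for cells that ovary samples could also hold, together with the comparisons, the tests and the rule for naming genes. Lists were compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list changes at all, without comparing it with other genes. A list needed 3 tested members. Another 2 lists, of nuclear-retained RNAs and of genes that escape X inactivation, were written after the data were examined. The named genes are the targeted genes Nr1h2, Nr1h3 and Amh, the 8 genes with the largest change in each direction, and up to 2 members of each list with the smallest adjusted p. The genes with the largest change had to be called, to have a mean RPKM of at least 1, and to have no overlap between the libraries of both groups. Clone-named genes were left out of that part of the rule. By chance, 10% of genes have no overlap between 3 and 3 libraries. Genes named outside this rule are said to be so. Some genes that the rule selects are not reported here.

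The fits were tested on simulated reads made from the mean of each gene over these libraries and its spread, with 100 genes changed by each fold. The changed genes had a mean RPKM of at least 1, and all groups had the same spread. Far fewer genes were changed than were called against WT below. The shares recovered and the false calls describe that setting only. For DKO against WT, 72% of genes changed 2-fold and 93% of genes changed 4-fold were recovered, with 3 false calls among 18375 genes. The shares were 73% and 88% for DKO_TG against DKO, with 5 false calls among 18392 genes. They were 66% and 93% for DKO_TG against WT, with 6 false calls among 18371 genes.

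The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at an RPKM of 1, TMM, TPM and quantile rescaling, array weights, the replicate number as a block, a fit of only the 6 libraries compared, and leaving out each library in turn. Added after the data were examined were limma-voom on the recovered reads, protein-coding genes only, a correction of each library for exon length and GC content, rescaling to the plain total of reads, and for the genes near Cav1 a filter on the mean RPKM in WT. Reads shared by near-identical genes and by genes with overlapping exons cannot be separated from these values, and genes named in the text whose exons overlap an annotated gene on either strand are given as uncertain. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, further tests and plots.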

Results

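Expression was measured by RNA sequencing in the ovaries of adult mice 40 h after PMSG, a gonadotropin that drives follicle growth. The 9 libraries fall into 3 genotypes of 3 libraries each: WT, DKO and DKO_TG. DKO is labelled as the double knockout of the liver X receptors, LXRa and LXRb. DKO_TG is the same knockout labelled as carrying an LXRb transgene under the name of Amh. Liver X receptors are nuclear receptors for oxysterols that control cholesterol efflux and lipid synthesis. The design asks what changes in the stimulated ovary without these receptors and which of the changes differ when the transgene is present. The WT libraries held 57.7, 48.6 and 53.7 M recovered reads, the DKO libraries 46.1, 59.2 and 59.4 M, and the transgene-labelled libraries 46.2, 40.1 and 47.6 M. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples.

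Both targeted receptor genes were low in the libraries labelled as knockout. On mm10, Nr1h3 lies on chromosome 2 at 91184061 to 91202834 (minus strand), Nr1h2 on chromosome 7 at 44549616 to 44553951 (minus strand) and Amh on chromosome 10 at 80805243 to 80807648 (plus strand). In replicates 1, 2 and 3, Nr1h3 was at 5.47, 4.12 and 4.45 RPKM in WT, 0.590, 1.11 and 0.717 in DKO, and 0.538, 0.824 and 0.647 in DKO_TG. Nr1h2 was at 22.5, 18.7 and 15.2 RPKM in WT, 7.79, 6.02 and 5.79 in DKO, and 5.14, 5.96 and 5.90 in DKO_TG. Nr1h3, which encodes LXRa, was thus at 4.68 ± 0.701 RPKM in WT, 0.807 ± 0.273 in DKO and 0.670 ± 0.145 in DKO_TG (SD, n = 3 each). Nr1h2, which encodes LXRb, was at 18.8 ± 3.64 RPKM in WT, 6.53 ± 1.09 in DKO and 5.67 ± 0.458 in DKO_TG (SD, n = 3 each). In limma both fell in DKO against WT, Nr1h3 with a 95% interval of the log2 change from -2.39 to -1.61 (adjusted p = 3.24e-05) and Nr1h2 with a log2 change of -1.45 ± 0.16 (SE, adjusted p = 0.000119). Both were also lower in DKO_TG than in WT, Nr1h3 by -2.15 and Nr1h2 by -1.63 (adjusted p = 2.32e-05 and 6.62e-05 in limma). Nr1h2 was not higher in the transgene-labelled libraries than in DKO: the log2 change was -0.18, with a 95% interval from -0.54 to 0.17 and an adjusted p of 0.621 in limma. The labels do not give the sequence of the transgene, so reads from it need not be counted under Nr1h2. The label of the transgene was therefore not checked by these values, and directions drawn for DKO_TG rest on the label. Amh, the anti-Müllerian hormone gene of growing follicles, was at 16.9 ± 4.59, 11.5 ± 3.93 and 9.77 ± 0.851 RPKM in WT, DKO and DKO_TG (SD, n = 3 each). In limma it was not called in DKO against WT (log2 change -0.56, adjusted p = 0.0992) and was lower in DKO_TG than in WT (log2 change -0.73, adjusted p = 0.0464). That call of Amh was lost without WT replicate 2 or 3 or without DKO_TG replicate 1, 2 or 3 (highest adjusted p = 0.148 in limma, without WT replicate 2). In DKO_TG against DKO the log2 change of Amh was -0.17 (adjusted p = 0.803 in limma). Nr1h3 shares exons with an annotated non-coding transcript on the same strand and is uncertain. The call of Amh against WT was also lost without a filter, with the replicate block, with TPM, quantile and plain total rescaling, and with the length and GC correction.

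**Figure D1:**
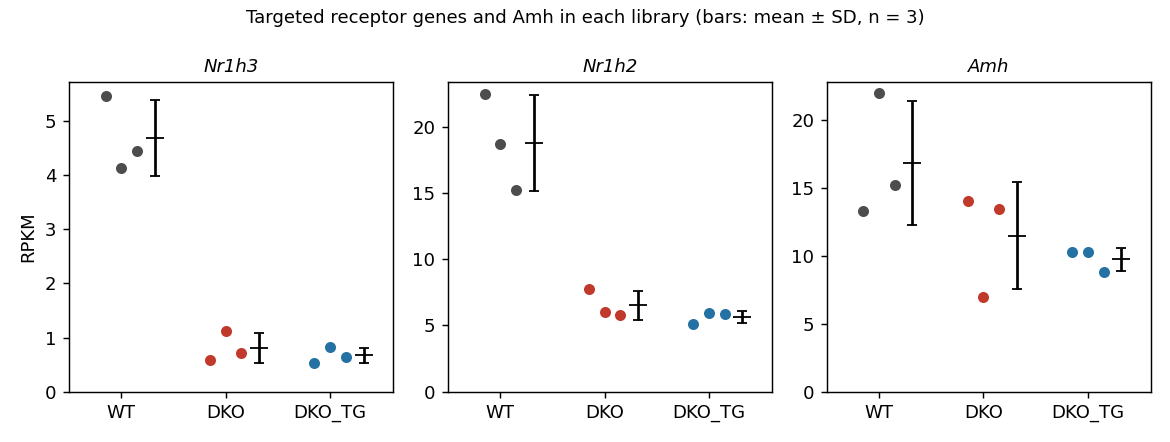
RPKM of Nr1h3, Nr1h2 and Amh in each of the 9 libraries, with the mean and SD of the 3 libraries of each genotype beside the points. Mean Nr1h2 was 18.8 RPKM in WT, 6.53 in DKO and 5.67 in DKO_TG.

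The WT libraries stood apart from the other 6 in the RNA classes they held. Malat1 and Neat1, long non-coding RNAs retained in the nucleus, were at 7.38 ± 5.03 and 0.577 ± 0.304 RPKM in WT, 199 ± 19.1 and 55.3 ± 12.7 in DKO, and 261 ± 16.4 and 58.4 ± 8.94 in DKO_TG (SD, n = 3 each). Of 1309 tested long non-coding genes, 892 were higher and 57 lower in DKO than in WT, and of 409 small non-coding genes 247 were higher and 34 lower. Of 3801 pseudogenes, 401 were higher and 1825 lower. Pseudogene reads made up 20.7% to 23.3% of each WT library and 14.9% to 18.3% of each other library; many are shared with the parent genes and are uncertain. The first principal component held 66.8% of the variance and separated WT from the other libraries. Correlations of log2 values were 0.987 to 0.993 within WT, 0.988 to 0.992 within DKO_TG and 0.968 to 0.975 within DKO, the group with the widest spread. Between DKO and DKO_TG libraries they were 0.962 to 0.976, so DKO libraries were about as close to DKO_TG as to each other. Between WT and DKO they were 0.912 to 0.944, and between WT and DKO_TG 0.936 to 0.950. WT genotype and these RNA class differences coincide, so every difference from WT below moves with them. Malat1 and Neat1 share exons with short annotated RNAs and are to that extent uncertain.

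In DKO ovaries 20 of 24 genes of cholesterol synthesis and uptake were lower and 12 of 19 macrophage markers higher than in WT. Camera in limma called both lists with the preset correlation and neither with an estimated one (adjusted p = 0.810 for each). That was also the lowest value over the 24 lists, so the estimated correlation does not tell lists apart here. Srebf2, the transcription factor that drives cholesterol synthesis genes, fell from 41.8 ± 8.98 to 20.2 ± 2.14 RPKM, and the sterol isomerase gene Ebp fell from 60.9 ± 24.3 to 20.2 ± 2.27 RPKM (SD, n = 3). Adgre1, which encodes the macrophage protein F4/80, rose from 2.83 ± 0.482 to 8.93 ± 3.19 RPKM (SD, n = 3). Scarb1, the receptor for high-density lipoprotein, fell from 405 ± 110 to 142 ± 69.4 RPKM, and Cyp11a1, which makes pregnenolone from cholesterol, fell from 3071 ± 677 to 1420 ± 385 RPKM (SD, n = 3). Cyp11a1 overlaps a non-coding gene on the same strand and is uncertain. Vegfa, which encodes the main growth factor of vascular permeability, rose from 10.2 ± 1.96 to 35.1 ± 9.99 RPKM (SD, n = 3; log2 change 1.72 ± 0.23 SE, adjusted p = 0.000359 in limma). With quantile normalization Scarb1 and Cyp11a1 were not called, nor was Cyp11a1 without a filter.

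Among 24 tested genes of cholesterol synthesis and uptake, 20 fell and 0 rose in DKO (21 and 0 when adjusted over the list alone; 21 at an unadjusted p under 0.05), with a median log2 change of -1.10. Srebf2 changed by -1.01 ± 0.15 and Ebp by -1.51 ± 0.23 (SE, adjusted p = 0.000654 and 0.000804 in limma). The list was lower than other genes by camera in limma (adjusted p = 1.24e-05), with an adjusted p = 0.810 with an estimated correlation. In the list of fatty acid synthesis, 9 of 15 fell (also 9 when adjusted over the list alone), among them Elovl5, a fatty acid elongase (log2 change -1.10), and Acly, which makes cytosolic acetyl-CoA (-1.14). The count of 9 was 5 without DKO replicate 2 and 5 without DKO replicate 3. By camera in limma that list had an adjusted p of 0.0302 and an adjusted p = 0.810 with an estimated correlation, and the call was lost without DKO replicate 3 (0.0640). Of 19 macrophage markers, 12 rose and 0 fell (12 and 0 when adjusted over the list alone), with Adgre1 at a log2 change of 1.46 and Itgam, the integrin CD11b, at 1.67. Itgam shares exons with an annotated neighbour and is uncertain. Camera in limma gave an adjusted p of 0.0286 for the macrophage list and an adjusted p = 0.810 with an estimated correlation. The globin genes, which mark red blood cells, summed to 359 to 1655 RPKM per WT library, 561 to 2405 per DKO library and 197 to 284 per DKO_TG library. In the cell cycle list 7 of 20 fell (6 when adjusted over the list alone), led by the replication licensing genes Mcm6 (log2 change -1.46) and Mcm3 (-0.87). Without DKO replicate 3 the count was 12. The list had an adjusted p by camera in limma of 0.0302 and an adjusted p = 0.810 with an estimated correlation, and the call was lost without DKO replicate 1 (0.125). Of 24 alternatives, 16 called the cell cycle list. The call of the fatty acid and cell cycle lists was lost with a filter at an RPKM of 1 (adjusted p = 0.0508 by camera in limma for both) and with quantile normalization (0.442 and 0.269), and that of the cell cycle list with fry (0.264). With TPM the mean of the cell cycle list turned to 0.12, and Elovl5 and Mcm3 were not called; quantile normalization also ended the call of Elovl5.

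The other lists were not called between DKO and WT by camera in limma, although single members were. Of all 18889 tested genes, 5821 were called higher and 4889 lower in this comparison. Counts near those shares do not set a list apart from other genes. In the list of LXR target genes Mertk, a phagocytic receptor, rose from 1.78 ± 0.147 to 4.51 ± 1.41 RPKM (SD, n = 3), and by log2 change Fasn (-0.62), Scd2 (-0.56) and Lpcat3 (-0.50) fell, out of 16 tested (1 higher and 1 lower when adjusted over the list alone). The median of that list was 0.02 and its mean 0.07, while camera pointed lower (adjusted p = 0.790 in limma). Srebf1, Abca1 and Abcg1, central LXR targets named after their values were seen, had log2 changes of 0.02, 0.56 and 0.40 and were not called. Lpcat3 and Scd2 were also named after their values were seen. Srebf1, Scd2 and Lpcat3 overlap annotated genes and are uncertain. Of 16 steroidogenesis genes 4 fell, also 4 when adjusted over the list alone: Scarb1 (log2 change -1.63), Cyp11a1 (-1.13) and, named after their values were seen, Star (-1.52) and Por (-0.83). Luteal cell markers had 1 of 14 higher, the cell cycle inhibitor gene Cdkn1b (1.28), and 5 lower, among them the prolactin receptor gene Prlr (-0.97), which overlaps an annotated neighbour and is uncertain (1 and 5 when adjusted over the list alone). Of 16 granulosa cell markers, the transcription factor gene Foxl2 fell by 0.51 and Nr0b1 rose by 0.63 on the log2 scale (0 higher and 1 lower when adjusted over the list alone). Foxl2 overlaps an antisense gene and is uncertain. The call of Nr0b1 was lost without any of 7 libraries, with adjusted p up to 0.127 in limma. Of 20 oocyte markers 9 rose (6 when adjusted over the list alone), with Npm2 at 1.53 and Khdc3 at 0.65, both overlapping annotated neighbours and uncertain. The direction of Khdc3 turned with quantile normalization, to -0.0907 (adjusted p = 0.634 in limma). The count of 9 was 3 without WT replicate 1, 2 without DKO replicate 1, 16 without DKO replicate 2 and 3 without DKO replicate 3. Theca and interstitial markers had 6 of 12 higher (also 6 when adjusted over the list alone). The first of them were Gli1 (1.82), a hedgehog target that overlaps Arhgap9, and Insl3 (1.38), which lies inside Jak3, so both are uncertain. Without DKO replicate 1, 3 theca markers were higher and 8 luteal markers were lower. Higher LXR targets were 2 without WT replicate 1 or DKO replicate 1. Steroidogenesis had 1 higher without WT replicate 1, and theca markers had 1 lower without WT replicate 1 or 2 or DKO replicate 3. Without DKO replicate 3, LXR targets had 3 higher and 1 lower and granulosa markers 2 lower, and without DKO replicate 2 granulosa markers had 3 higher. With TPM the direction of Foxl2 turned, to 0.0355, and Fasn and Prlr were not called. Quantile normalization ended the calls of Fasn, Foxl2, Prlr, Nr0b1, Scarb1 and Cyp11a1, and the plain total of reads those of Fasn and Foxl2. Nr0b1 was also not called without a filter, with TMM, with voom, with the replicate block or in the fit of 6 libraries, and Cyp11a1 was not called without a filter.

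Endothelial markers split, with 3 of 18 higher and 9 lower (also 3 and 9 when adjusted over the list alone). Egfl7 (log2 change 1.92) overlaps Agpat2 and is uncertain, and Plvap, a protein of fenestrated endothelium, changed by -1.08. The list of vascular permeability genes had 7 of 22 higher and 7 lower, the same numbers when adjusted over the list alone. These are near the shares of all genes, 5821 higher and 4889 lower of 18889. Of 10 inflammatory genes 5 rose and 1 fell (5 and 1 when adjusted over the list alone), with the neutrophil chemokine gene Cxcl1 at 1.23 and Tgfb1 at -1.07. Of 8 other leukocyte markers 5 rose, also 5 when adjusted over the list alone, with Ptprc, which encodes CD45, at 2.20 and the B cell gene Cd79b at 1.72. Fibroblast and matrix genes had 7 of 14 lower (also 7 when adjusted over the list alone), among them Col6a1 (-0.85) and Sparc (-1.14). In smooth muscle 3 of 10 were lower (also 3 when adjusted over the list alone), namely Myl9 (-1.03), Des (-0.52) and, named after its value was seen, Acta2 (-0.71). The call of Des was lost without WT replicate 2 or DKO replicate 3 (highest adjusted p = 0.0614 in limma). In lipid storage 4 of 14 fell (also 4 when adjusted over the list alone), Pnpla2 by 0.58 and Nceh1 by 0.43 on the log2 scale, and, named after their values were seen, Npc2 by 0.59 and Npc1 by 0.34. In apoptosis 6 of 15 rose and 3 fell (6 and 3 when adjusted over the list alone). Among those that fell was Bak1 (-0.90), which lies inside Ggnbp1 and is uncertain. The ovulation list had 2 of 10 lower (also 2 when adjusted over the list alone), Adamts4 (-0.56), uncertain for an overlap, and Ctsl (-0.91). Immediate-early genes had 2 of 9 higher and 2 lower (2 and 2 when adjusted over the list alone), with Fos at 0.84 and Egr1 at -0.99. Of 4 adipocyte markers 2 fell (also 2 when adjusted over the list alone), Car3 (-1.67) and Plin1 (-0.97), the latter not called without WT replicate 1, DKO replicate 1 or 2, or any DKO_TG library (highest adjusted p = 0.126 in limma). Of 3 oviduct markers Ovgp1 (1.23) and Tppp3 (0.84) rose and Rsph1, named after its value was seen, fell by 0.60 on the log2 scale (2 and 1 when adjusted over the list alone). The call of Tppp3 was lost without WT replicate 2 or 3 (highest adjusted p = 0.0815 in limma). That of Rsph1 was lost too, with 0 lower oviduct markers without WT replicate 1, 2 or 3 or DKO replicate 3. In limma 0 of 9 ovarian surface epithelium markers and 0 of 5 erythrocyte genes were called, 0 of each at an unadjusted p under 0.05 and 0 of each when adjusted over the list alone. Lgals7 of the epithelium list had a log2 change of -0.59 and Alas2 of the erythrocyte list, which overlaps Apex2, was at 3.59 ± 2.07 RPKM in DKO and 1.69 ± 0.735 in WT (SD, n = 3). Median, mean and camera differed in sign for the granulosa, ovulation, vascular, apoptosis, immediate-early and LXR target lists. None of the 13 mitochondrially encoded genes could be tested. Without WT replicate 2 the lower genes were 4 for vascular permeability, 4 for fibroblast and matrix, 1 for smooth muscle and 2 for surface epithelium, and without WT replicate 3 they were 4 for vascular permeability and 3 for fibroblast and matrix. For fibroblast and matrix genes they were 4 without DKO replicate 1 and 4 without DKO replicate 3. Without DKO replicate 2 there were 3 higher inflammatory, 5 lower smooth muscle and 7 lower apoptosis genes, and without DKO replicate 3 there were 3 higher inflammatory and 1 lower smooth muscle gene. Immediate-early genes had 1 lower without DKO replicate 1 or 3. Among lists with 0 in that direction, 1 lipid storage gene was higher without DKO replicate 2, 1 ovulation gene was higher without DKO replicate 2 or 3, 1 surface epithelium marker was lower without DKO replicate 3 and 1 erythrocyte gene was higher without DKO replicate 1. Des, Ctsl, Ovgp1, Npc1 and Alas2 share exons with annotated genes and are uncertain. With TPM the direction of Nceh1 turned, to 0.10, and Pnpla2, Adamts4, Ctsl, Myl9, Des, Col6a1 and Plin1 were not called. Quantile normalization ended the calls of Ctsl, Myl9, Col6a1, Sparc, Tppp3 and Fos, and the plain total of reads those of Pnpla2, Nceh1, Des and Plin1. Plin1 and Tppp3 were also not called without a filter or in the fit of 6 libraries, nor Plin1 with array weights or the replicate block.

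**Figure D2:**
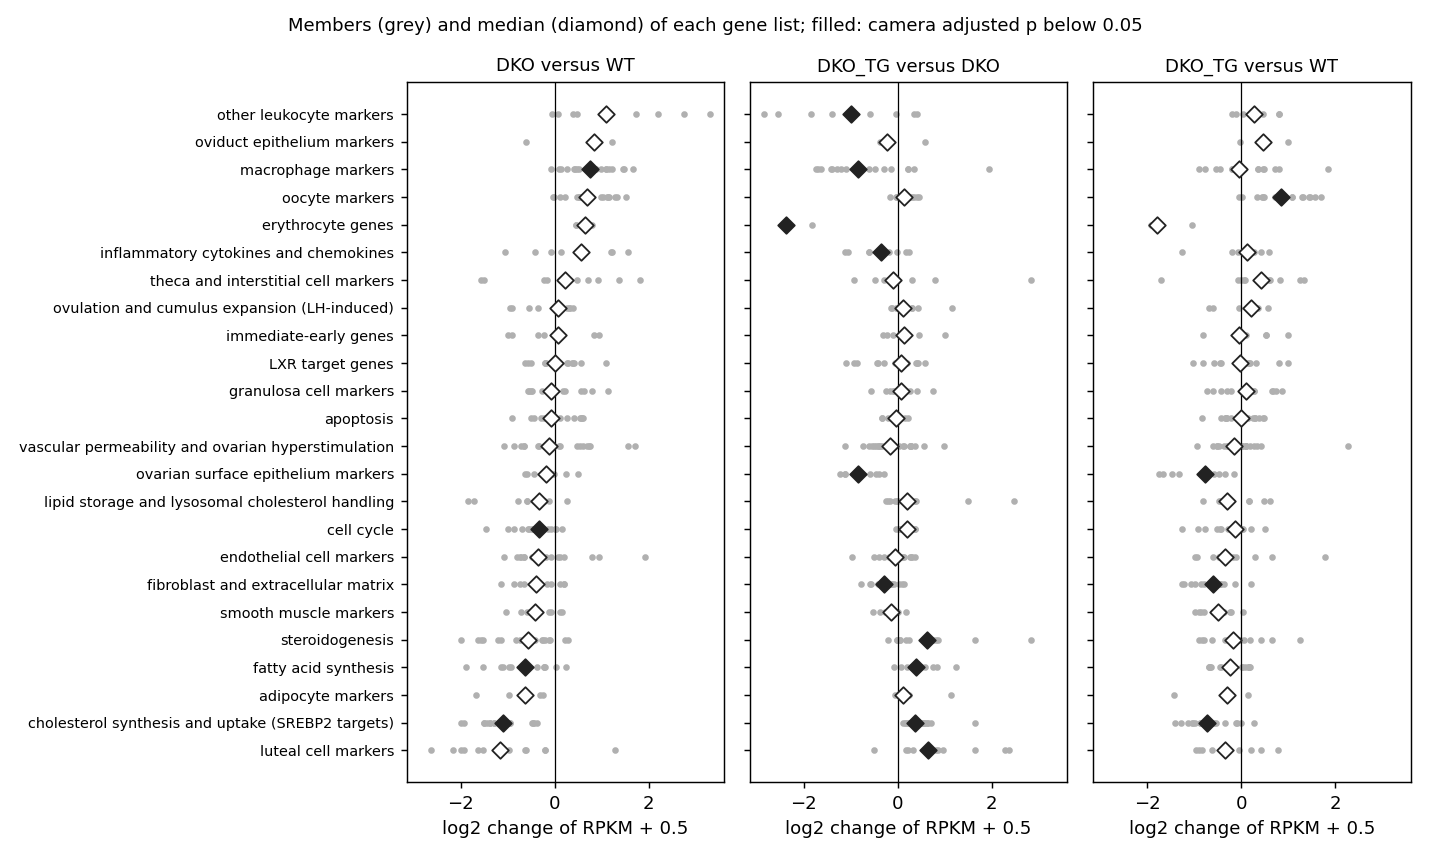
Log2 change of each tested member (grey points) and the median (diamonds) of 24 gene lists in the 3 comparisons, on the scale of log2(RPKM + 0.5). Filled diamonds mark the 4, 10 and 4 lists with a camera adjusted p under 0.05; the median of cholesterol synthesis and uptake was -1.10, 0.37 and -0.73 from left to right.

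In all, limma called 5821 genes higher and 4889 lower in DKO than in WT, 2221 and 754 of them by more than 2-fold. The share called higher was 54.4% and rested on the scaling. It was 91.2% after rescaling to TPM, which moved the median of all genes by 0.54 on the log2 scale, and 78.4% with the plain total of reads, which moved it by 0.29. With TMM, quantile normalization and the correction for length and GC it was 45.6%, 46.8% and 45.5%, so that more genes were called lower than higher. Changes against WT are therefore relative to the typical gene of the deposited scaling. The largest increases among named genes after Mir5125 were Neat1 (log2 change 5.71), Firre (5.15), Rgs11 (5.13), Malat1 (4.98), Mir351 (4.89) and the B cell chemokine gene Cxcl13 (4.83 ± 0.94 SE). Rgs11 overlaps Arhgdig on the other strand and is uncertain. Mir5125, inside an intron of Srrm2, and Snord123, inside Snhg18, were listed at 0 in WT and at 47.4 to 79.9 and 8.25 to 13.6 RPKM in the DKO libraries. The largest decreases after Mir7688 were Atp12a (-4.09), Psca (-4.04), Mir6236 (-3.76), Ly6k (-3.70), Nrcam (-3.54), Lars2 (-3.49) and Sstr1 (-2.93). Atp12a and Ly6k have overlapping antisense genes and are uncertain. Mir7688 was at 6.39 to 14.8 RPKM in the WT libraries and listed at 0 in DKO. With voom Cxcl13 was not called (adjusted p = 0.0530 in limma).

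In the transgene-labelled ovaries, Cav1 and Cav2, neighbouring genes for the caveolins of membrane pits, were far lower than in DKO. Of 19 macrophage markers 8 were lower too, and 0 without DKO_TG replicate 1, 2 or 3. Camera in limma called that list with the preset correlation but not with an estimated one (adjusted p = 0.467). Cav1 was at 37.3 ± 2.13 RPKM in DKO and 0.0871 ± 0.038 in DKO_TG, beside 38.1 ± 4.08 in WT (SD, n = 3; log2 change of DKO_TG against DKO -6.01 ± 0.10 SE, adjusted p = 1.59e-08 in limma). C1qc and C1qb, complement genes of macrophages, fell from 40.7 ± 15.4 to 11.2 ± 0.162 RPKM and from 104 ± 36.9 to 30.2 ± 2.77 RPKM (SD, n = 3). The Fc receptor gene Fcgr4 fell from 61.8 ± 45.4 to 2.23 ± 0.531 RPKM (SD, n = 3; log2 change -4.15 ± 0.62 SE, adjusted p = 0.0176 in limma). Lrrn3 rose from 0.846 ± 0.193 to 4.34 ± 0.229 RPKM, and Hspd1, the mitochondrial chaperonin, from 249 ± 46.7 to 675 ± 18.4 RPKM (SD, n = 3). In the fit of the 6 libraries compared C1qc, C1qb and Fcgr4 were not called, nor was Fcgr4 with voom or the replicate block.

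Cav1 lies on chromosome 6 at 17306335 to 17341452 of mm10, just beyond Cav2 at 17281185 to 17289115, both on the plus strand. Cav2, which was named after its value was seen in this comparison, was at 11.4 ± 1.34 RPKM in DKO and 1.87 ± 0.0429 in DKO_TG (SD, n = 3; log2 change -2.32, adjusted p = 4.03e-05 in limma). In WT it was at 17.6 ± 1.55 RPKM (SD, n = 3), so Cav2 was already lower in DKO than in WT. That log2 change was -0.60 (adjusted p = 0.00135 in limma), whereas Cav1 was not called in DKO against WT (-0.03, adjusted p = 0.832). Of 7 other tested genes within 0.5 Mb of Cav1, D830026I12Rik (-1.06) and Gm4876 (-1.05) were lower, and Tes (-0.43), Met (-0.53) and Capza2 (-0.11) were not called. Unlike Cav1 and Cav2, these 2 lower neighbours were also low in WT: D830026I12Rik was at 0.0576 ± 0.0224 RPKM in WT, 0.591 ± 0.0314 in DKO and 0.0241 ± 0.0209 in DKO_TG, and Gm4876 at 0.262 ± 0.0979, 0.709 ± 0.0539 and 0.0854 ± 0.0574 (SD, n = 3 each). Gm4876 and Tes overlap on opposite strands and D830026I12Rik overlaps an antisense gene, so all 3 are uncertain.

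**Figure D3:**
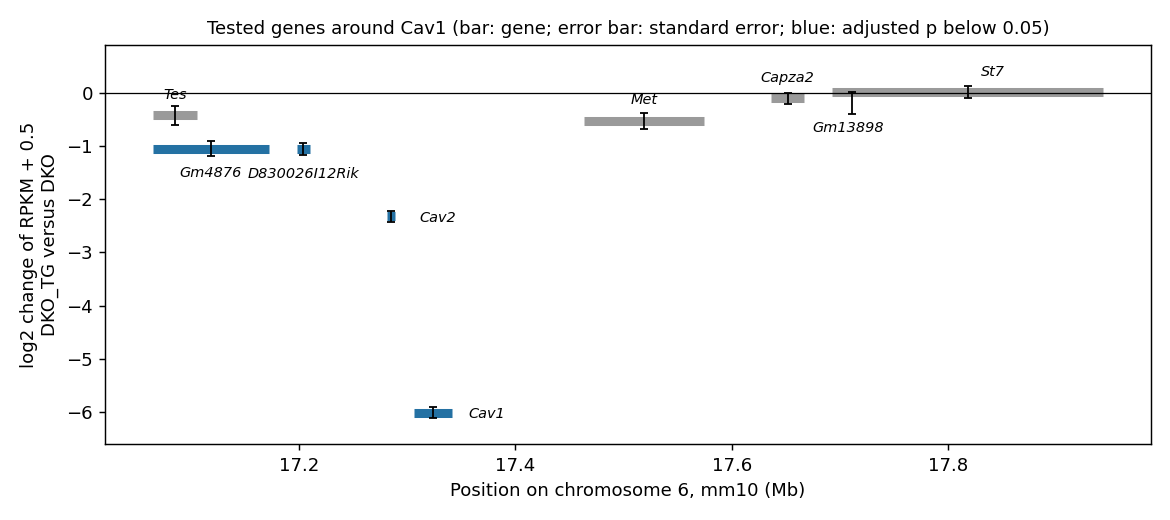
Log2 change in DKO_TG against DKO, on the scale of log2(RPKM + 0.5), for the tested genes within 0.5 Mb of Cav1 on chromosome 6 of mm10, each drawn at its position with its standard error. Cav1 (-6.01) and Cav2 (-2.32) lie lowest, and blue bars have an adjusted p under 0.05.

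Of 19 macrophage markers 8 fell and 0 rose in DKO_TG against DKO (11 and 1 when adjusted over the list alone), with a median log2 change of -0.85, C1qc at -1.74 and C1qb at -1.71. The count of 8 was 0 without DKO_TG replicate 1, 2 or 3, 4 and 3 without DKO replicate 2 or 3, and 5 without WT replicate 2. Camera in limma gave the list an adjusted p of 1.92e-08, and an adjusted p = 0.467 with an estimated correlation. Of 8 other leukocyte markers Ptprc (-1.40) and Cd79b (-1.84) fell (0 higher and 5 lower when adjusted over the list alone; camera in limma adjusted p = 0.00628, and adjusted p = 0.467 with an estimated correlation). Of 10 inflammatory genes Icam1, an adhesion molecule, fell by 0.61 on the log2 scale (4 lower when adjusted over the list alone; camera in limma adjusted p = 0.00343, and adjusted p = 0.467 with an estimated correlation). The 2 leukocyte markers were 0 without DKO replicate 3 or any DKO_TG library, 1 without WT replicate 2 or 3 or DKO replicate 2, and 4 without DKO replicate 1. The call of Icam1 was lost without WT replicate 2 or 3, DKO replicate 2 or 3 or any 1 DKO_TG library (highest adjusted p = 0.142 in limma). Icam1 overlaps an antisense gene and is uncertain, and the call of the inflammatory list was lost without DKO replicate 2 (0.0805). In limma 0 of 5 erythrocyte genes were called in this comparison, with 5 at an unadjusted p under 0.05 and 5 lower when adjusted over the list alone; without DKO replicate 1, 5 were called. Their median was -2.38 (camera in limma adjusted p = 4.22e-05, and adjusted p = 0.467 with an estimated correlation), with Alas2 at -1.83. Dcn, a matrix proteoglycan gene, fell by 0.78 on the log2 scale, 1 of 14 fibroblast and matrix genes (2 when adjusted over the list alone). Its call was lost without DKO replicate 3 or any 1 DKO_TG library (highest adjusted p = 0.0923 in limma). Camera in limma gave the matrix list an adjusted p of 0.00181 and an adjusted p = 0.467 with an estimated correlation. In limma 0 of 9 surface epithelium markers were called (4 at an unadjusted p under 0.05, and 4 lower when adjusted over the list alone), with a median of -0.84; 1 was called lower without DKO replicate 1. That epithelium list was lower by camera in limma (adjusted p = 0.000111, and adjusted p = 0.467 with an estimated correlation). In the fit of the 6 libraries compared C1qc, C1qb, Ptprc, Cd79b, Icam1 and Dcn were not called. With the replicate block Ptprc, Cd79b, Icam1 and Dcn were not, without a filter Ptprc, Cd79b and Icam1, with voom Cd79b, and with the length and GC correction Icam1.

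The lists of cholesterol synthesis, fatty acid synthesis, steroidogenesis and luteal markers were higher in DKO_TG than in DKO by camera with the preset correlation, while 0 of their members were called by limma. With an estimated correlation none of the 4 was called, with camera in limma at an adjusted p = 0.669 for cholesterol synthesis and luteal markers and an adjusted p = 0.467 for fatty acid synthesis and steroidogenesis. For cholesterol synthesis the median was 0.37, with 3 of 24 members at an unadjusted p under 0.05, and 0 when adjusted over the list alone. The test by camera in limma had an adjusted p of 0.000273, and an adjusted p = 0.669 with an estimated correlation; without DKO replicate 3 it was 0.0509. Without WT replicate 1 or DKO replicate 1, 1 cholesterol gene was called higher. For fatty acid synthesis the median was 0.39, with 4 of 15 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera in limma adjusted p = 0.000858, and adjusted p = 0.467 with an estimated correlation). Without WT replicate 1, 2 of them were called higher. For steroidogenesis the median was 0.61, with 4 of 16 at an unadjusted p under 0.05 and 1 when adjusted over the list alone (camera in limma adjusted p = 0.0138, and adjusted p = 0.467 with an estimated correlation). That call was lost without DKO replicate 2 (0.0823), and 1 steroidogenesis gene was called higher without WT replicate 1. Cyp17a1, the androgen-making enzyme of theca cells, was at 118 ± 73.4 RPKM in DKO, 752 ± 180 in DKO_TG and 437 ± 450 in WT (SD, n = 3). Its log2 change of 2.82 in DKO_TG against DKO was not called by limma (adjusted p = 0.0724), but was without WT replicate 1 (0.0267), the WT library at 956 RPKM. That library is in neither compared group and enters through the shared estimate of spread. Cyp17a1 was called in 4 of 22 alternatives, with an adjusted p of 0.0267 to 0.214 in limma. For luteal markers the median was 0.64, with 3 of 14 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Camera in limma gave an adjusted p of 0.0113 for them and an adjusted p = 0.669 with an estimated correlation, and 0.257 without DKO replicate 3. Of 24 alternatives, 20 called the luteal list. The fry test, also in limma, called 0 of the 24 lists in this comparison.

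Among the lists that camera did not call, Pltp, an LXR target and phospholipid carrier that overlaps Ctsa and is uncertain, fell from 8.75 ± 2.30 to 3.73 ± 0.169 RPKM (SD, n = 3). It was 1 of 16 LXR targets (2 higher and 2 lower when adjusted over the list alone), and the median of that list was 0.06 and its mean -0.11. Vwf, the von Willebrand factor gene, fell by 0.98 on the log2 scale, 1 of 18 endothelial markers (also 1 when adjusted over the list alone), and Icam1 was 1 of 22 vascular permeability genes (1 higher and 4 lower when adjusted over the list alone). Without any 1 DKO_TG library the calls of Pltp and Vwf were lost (highest adjusted p = 0.0943 and 0.0800 in limma), that of Vwf also without DKO replicate 3, and Icam1 was not called without any 1 of 7 libraries. Without DKO replicate 1, 1 vascular permeability gene was higher, and without WT replicate 1, 1 theca marker and 1 immediate-early gene were higher. For theca and interstitial markers the median was -0.11 and the mean 0.12. In limma 0 members were called in the other lists. For these the numbers at an unadjusted p under 0.05 were 4 of 12 for theca (Insl3 -0.93, inside Jak3; 1 higher and 1 lower when adjusted over the list alone), 0 of 14 for lipid storage (Plin4 2.46), 1 of 16 for granulosa (Nr0b1 -0.57), 0 of 10 for ovulation (Runx2 1.15) and 1 of 20 for oocyte markers (Gtsf1 0.46). They were 1 of 10 for smooth muscle (Des -0.38), 0 of 20 for the cell cycle (Ccnb1 0.26), 2 of 15 for apoptosis (Bcl2l1 -0.33), 1 of 4 for adipocytes (Plin1 1.13; 1 higher when adjusted over the list alone), 1 of 3 for oviduct (Rsph1 0.57) and 1 of 9 for immediate-early genes (Nr4a1 at 15.5 ± 1.57 against 7.59 ± 1.75 RPKM, SD, n = 3). Lists with no count given had 0 when adjusted over the list alone. Insl3, Plin4, Runx2 and Des overlap annotated genes and are uncertain. Pltp was not called with the replicate block or in the fit of the 6 libraries compared.

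In all, limma called 94 genes higher and 327 lower in DKO_TG than in DKO, 35 and 173 of them by more than 2-fold, and 2987 genes had an unadjusted p under 0.05. The count rested on the shared estimate of spread and on single libraries. It was 57 in a fit of the 6 libraries compared, and 32, 31 and 33 without DKO_TG replicate 1, 2 or 3. Without DKO replicate 2 or 3 it was 212 and 136, and without WT replicate 2 or 3 it was 198 and 247. Of 24 named calls, 3 were kept without each library in turn: Cav1, Lrrn3 and Hspd1-ps5. The other increases were Alas1 (log2 change 1.82), Mir6993 (1.68), which lies inside Fads1, Hspd1-ps3 (1.46), Hspd1 (1.45), Hspd1-ps5 (1.45), Cyfip2 (1.39) and Tubb3 (1.33). Hspd1 and its pseudogenes share reads and are uncertain. The decreases after Cav1 were Cxcl13 (-4.99), Fcgr4 (-4.15), Cd300e (-3.81), the immunoglobulin gene Ighg1 (-3.77), Sirpb1a (-3.08), Clec4a3 (-3.01) and Fpr2 (-2.98). Alas1 and Fpr2 overlap annotated genes and are uncertain. Several of these decreases belong to families of similar genes whose reads can be shared. In the fit of 6 libraries Mir6993, Cxcl13, Fcgr4, Cd300e, Ighg1, Sirpb1a, Clec4a3 and Fpr2 were not called. With voom Cxcl13, Fcgr4, Cd300e, Sirpb1a, Clec4a3 and Fpr2 were not, with the replicate block Alas1, Mir6993, Cyfip2, Tubb3, Cxcl13 and Fcgr4, without a filter Alas1, Tubb3, Cxcl13 and Sirpb1a, and with the length and GC correction Alas1.

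**Figure D4:**
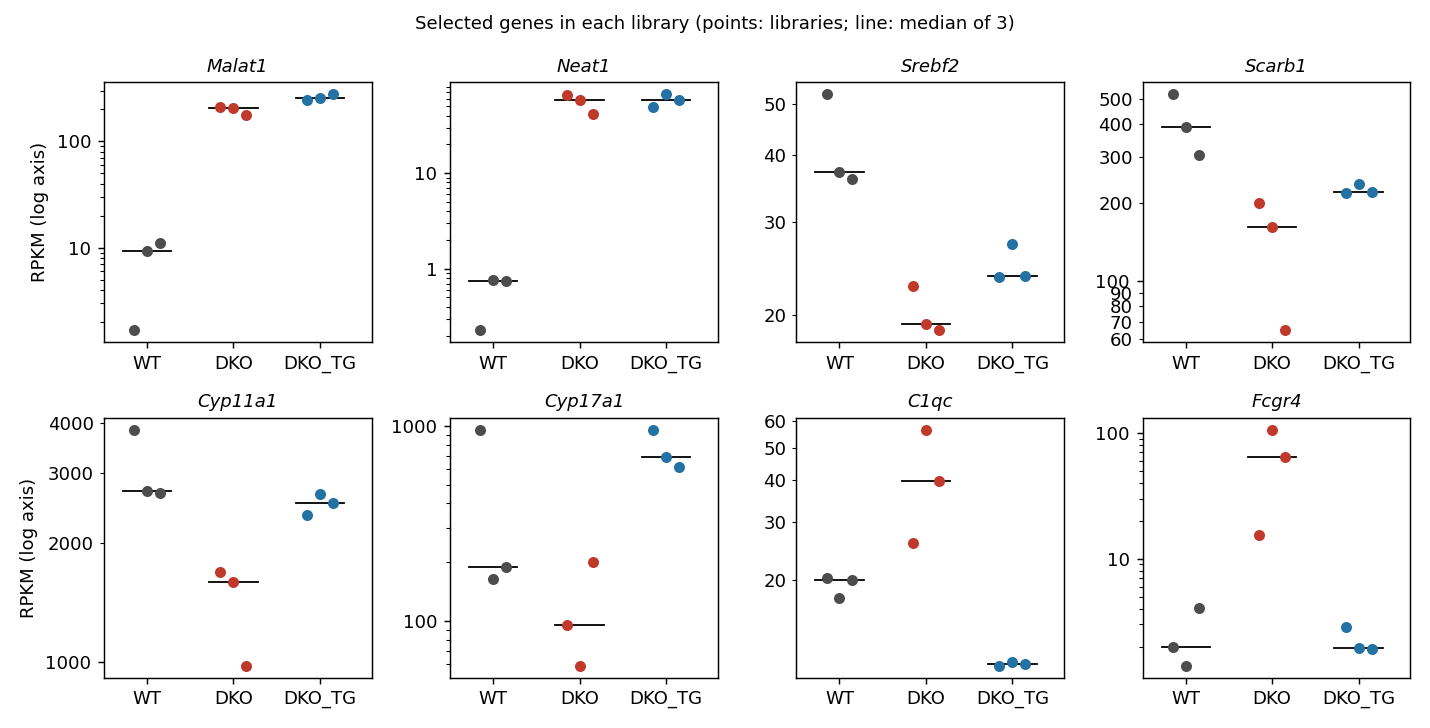
RPKM of 8 genes in each of the 9 libraries on log axes, with a line at the median of each genotype. Cyp17a1 was at 59.0 to 200 RPKM in the DKO libraries and 612 to 955 in the DKO_TG libraries, while 1 WT library was at 956.

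Against WT, the transgene-labelled ovaries had more Neat1, Malat1 and Firre, as the DKO ovaries had, and very little Cav1. In limma 11 of 24 cholesterol synthesis genes were called lower, beside 20 of 24 in DKO against WT, and camera had an adjusted p = 0.829 with an estimated correlation. Compared directly, DKO_TG against DKO, 0 of the 24 were called, so the counts of 11 and 20 alone do not show a return. Srebf2 was at 24.8 ± 2.08 RPKM in DKO_TG and 41.8 ± 8.98 in WT, and Ebp at 21.8 ± 2.12 and 60.9 ± 24.3 RPKM (SD, n = 3). Vegfa was at 51.0 ± 7.39 RPKM against 10.2 ± 1.96 in WT (SD, n = 3; log2 change 2.28 ± 0.23 SE, adjusted p = 8.26e-05 in limma). Rpl29, a ribosomal protein gene, was at 22.9 ± 0.342 RPKM against 145 ± 6.66 in WT (SD, n = 3; log2 change -2.63, adjusted p = 5.45e-07 in limma), beside at most 27.4 RPKM in the DKO libraries. With TPM Srebf2 was not called against WT.

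Of 24 cholesterol genes 11 fell and 0 rose in DKO_TG against WT (11 and 0 when adjusted over the list alone), with a median of -0.73, Ebp at -1.40 and Srebf2 at -0.72. The count of 11 was 7 without DKO_TG replicate 1 and 7 without DKO_TG replicate 3. Camera in limma gave the list an adjusted p of 0.00159 and an adjusted p = 0.829 with an estimated correlation. Of 14 fibroblast and matrix genes 9 fell (also 9 when adjusted over the list alone), with Col6a1 at -0.98 and Bgn at -1.06 (camera in limma adjusted p = 0.00159, and adjusted p = 0.829 with an estimated correlation). Of 9 surface epithelium markers 6 fell (also 6 when adjusted over the list alone), with the keratin gene Krt19 at -1.66 and Cldn15 at -0.76 (camera in limma adjusted p = 0.0271, and adjusted p = 0.829 with an estimated correlation). Of 20 oocyte markers 11 rose (13 when adjusted over the list alone), with Npm2 at 1.56 and Khdc3 at 0.80, both uncertain for their overlaps. The oocyte list had by camera in limma an adjusted p of 0.0271 and an adjusted p = 0.829 with an estimated correlation, and the call was lost without WT replicate 1 (0.0800). The oocyte count was 5 without WT replicate 1 and 4 without DKO_TG replicate 1 or 3, and the epithelium count was 3 without WT replicate 1. Quantile normalization ended the call of the cholesterol, matrix and oocyte lists and of Col6a1 and Khdc3, and TPM that of the oocyte list and of Srebf2 and Cldn15. The oocyte list was also not called with the plain total of reads, nor the epithelium list with TMM or the length and GC correction, and fry did not call the cholesterol, oocyte and epithelium lists.

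Single members of other lists were called too, beside 5491 higher and 4214 lower among all 18889 tested genes. Counts near those shares do not set a list apart from other genes. Mertk (0.80) and, named after its value was seen, Abca1 (1.00), the cholesterol efflux transporter, were higher among 16 LXR targets. Apoe (-1.03), Pltp (-0.81), Fasn (-0.43) and, named after its value was seen, Lpcat3 (-0.57) were lower, and the counts were also 2 and 4 when adjusted over the list alone. The call of Fasn was lost without WT replicate 1 or any DKO_TG library (highest adjusted p = 0.0990 in limma). Of 16 steroidogenesis genes Por fell by 0.79 on the log2 scale (0 when adjusted over the list alone). Foxl2 (-0.59), Des (-0.90), Acta2 (-0.98), Eng (-0.99), Tgfb1 (-1.25), Mcm6 (-1.25), Mcm5 (-0.91), Bak1 (-0.84), Pnpla2 (-0.80) and Egr1 (-0.80) were lower. Nr2f2 (0.59), Gli1 (1.33), Atf3 (0.99), Ovgp1 (0.99) and Gpnmb (1.85), a lysosomal protein gene, were higher. Among these genes Foxl2, Des, Eng, Bak1, Lpcat3, Pltp, Nr2f2, Gli1 and Ovgp1 overlap annotated genes and are uncertain. The call of Gpnmb was lost without WT replicate 2 (adjusted p = 0.0563 in limma). The alpha globin gene Hba-a1 fell by 1.92 on the log2 scale, 1 of 3 erythrocyte genes called lower among 5 (5 when adjusted over the list alone). Its call was lost without WT replicate 1 or 2 or any DKO_TG library (highest adjusted p = 0.0954 in limma). Reads of Hba-a1 can be shared with Hba-a2 and are uncertain. The counts of higher and lower genes (in brackets those when adjusted over the list alone) were 0 and 1 (0 and 0) of 15 for fatty acid synthesis, 0 and 4 (0 and 3) of 14 for lipid storage, 0 and 2 (0 and 1) of 16 for granulosa and 0 and 2 (0 and 2) of 10 for ovulation. They were 1 and 0 (0 and 0) of 14 for luteal, 3 and 0 (3 and 0) of 12 for theca, 1 and 7 (1 and 7) of 18 for endothelial, 1 and 4 (1 and 3) of 22 for vascular, 3 and 3 (3 and 2) of 19 for macrophage and 2 and 0 (2 and 0) of 8 for other leukocyte genes. They were 1 and 1 (1 and 1) of 10 for inflammatory, 0 and 4 (0 and 3) of 10 for smooth muscle, 0 and 4 (0 and 3) of 20 for cell cycle, 3 and 4 (3 and 4) of 15 for apoptosis, 0 and 1 (0 and 1) of 4 for adipocyte, 1 and 0 (1 and 0) of 3 for oviduct and 2 and 1 (1 and 1) of 9 for immediate-early genes. Median, mean and camera differed in sign for the granulosa, ovulation, macrophage, inflammatory and immediate-early lists. The 7 lower endothelial genes were 4 without WT replicate 1 and 3 without WT replicate 2 or DKO_TG replicate 2 or 3, and the 4 lower vascular genes were 7 without DKO replicate 3. Lower LXR targets were 2 without WT replicate 1 or DKO_TG replicate 1 or 3, and lower lipid storage genes were 2 without WT replicate 1 or 3 or DKO_TG replicate 1 or 2 and 1 without DKO_TG replicate 3. Macrophage genes had 1 higher without WT replicate 2, 0 lower without WT replicate 3 or DKO_TG replicate 2, and 1 lower without DKO_TG replicate 1 or 3. Apoptosis genes had 1 higher without each DKO_TG library and 2 lower without DKO_TG replicate 2 or 3. Lower erythrocyte genes were 0 without WT replicate 1 or 2 or any DKO_TG library and 5 without DKO replicate 1, and lower steroidogenesis genes were 2 and 3 without DKO replicate 1 or 3. Higher leukocyte markers were 0 without DKO_TG replicate 1 and 1 without DKO_TG replicate 2 or 3, and higher luteal markers were 0 without DKO_TG replicate 1, 2 or 3. Lower luteal markers were 1 without DKO replicate 1 and 2 without DKO replicate 3 or DKO_TG replicate 2. Higher LXR targets were 1 without WT replicate 2 or 3 or DKO_TG replicate 1. Lower fatty acid genes were 0 without WT replicate 1 or any 1 DKO_TG library and 2 without WT replicate 3 or DKO replicate 3. Lower granulosa markers were 1 without WT replicate 2 or 3 or any 1 DKO_TG library, and lower ovulation genes were 1 without DKO_TG replicate 1. Higher endothelial genes were 2 without DKO replicate 1 or 3, higher vascular genes 2 without DKO replicate 1 or 2, and higher oviduct markers 2 without DKO replicate 3. Inflammatory genes had 0 higher without DKO replicate 3, adipocyte markers 0 lower without WT replicate 1 or DKO_TG replicate 1, and immediate-early genes 1 higher without WT replicate 1 or 3, DKO replicate 3 or any 1 DKO_TG library. Where 0 were called, WT replicate 1 left out gave 1 higher fatty acid gene, 1 higher steroidogenesis gene and 1 lower theca marker, DKO replicate 2 left out gave 1 higher lipid storage gene, and DKO replicate 3 left out gave 1 higher granulosa marker and 2 higher ovulation genes. Of 61 named calls in this comparison, 49 were kept without each library in turn. With TPM the direction of Fasn turned, to 0.0924, and Pltp, Por, Foxl2, Des, Acta2, Mcm5, Pnpla2, Egr1 and Hba-a1 were not called. Quantile normalization ended the calls of Mertk, Apoe, Fasn, Foxl2, Acta2, Atf3, Ovgp1 and Hba-a1, and the plain total of reads those of Fasn and Foxl2. Without a filter Fasn and Hba-a1 were not called.

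In all, limma called 5491 genes higher and 4214 lower in DKO_TG than in WT. The share called higher was 56.6%, beside 91.6% after rescaling to TPM (shift of all genes 0.52) and 77.3% with the plain total of reads (shift 0.26). It was 44.4% with TMM, 45.6% with quantile normalization and 45.4% with the correction for length and GC. The largest increases among named genes after Mir5125 were Neat1 (5.81), Malat1 (5.38), Firre (5.04), Xist (4.78) and Mir351 (4.77). Xist overlaps Tsix and is uncertain, and it was not called with voom or without a filter. The call of Xist was lost without WT replicate 1 or any DKO_TG library (highest adjusted p = 0.0737 in limma). The lowest adjusted p in limma on leaving out 1 library was 9.98e-06. Xist differed widely between the DKO libraries, which enter the shared estimate of spread, so the loss need not come from the WT or DKO_TG libraries. Snord72, inside an intron of Rpl37, rose by 4.22 on the log2 scale, and Mir5125 and Snord37, inside introns of Srrm2 and Eef2, were listed at 0 in WT and at 75.5 to 93.3 and 7.69 to 10.7 RPKM in the DKO_TG libraries. The largest decreases were Cav1 (-6.04), Psca (-3.95), Nefh (-3.34), Atp12a (-3.24), Cav2 (-2.93), Sstr1 (-2.89) and Rpl29 (-2.63). Mir7688, listed at 0 in DKO_TG, lay between Cav1 and Psca.

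Many genes called between DKO and WT were also called between DKO_TG and WT. Of the 10710 genes called in DKO against WT, 8295 were called in the same direction in DKO_TG against WT, 4759 higher and 3536 lower, where independent lists would share 1692 and 1091. Lists of the same sizes from 100 simulations of unchanged groups that share the WT libraries had on average 2982 and 2184 in common. The median share of the log2 difference that remained was 0.907, beside 0.480 to 0.520 in those simulations. Of the same genes, 319 were called in the opposite direction in DKO_TG against DKO, and 219 of those were no longer called against WT. They were 265 genes higher in DKO that fell in DKO_TG, where independent lists would share 101, and 54 genes lower in DKO that rose, where independent lists would share 24.3. In the simulations, where DKO libraries are shared, lists of the same sizes had 241 to 285 and 64 to 86 genes in common. The overlap of 265 genes lies inside its range and that of 54 below it. The simulated groups held no differences, so their lists are ranked by noise, unlike the real calls. The simulations therefore do not decide how much of either overlap comes from the shared libraries. Without DKO_TG replicate 1, 2 or 3 the count of 319 was 25, 25 and 26. Without DKO replicate 2 or 3 it was 172 and 101, and without WT replicate 2 or 3 it was 148 and 187. Across genes, which are not independent replicates, the DKO minus WT changes correlated with the DKO_TG minus DKO changes at -0.38, beside -0.50 for simulated unchanged groups that share the DKO libraries. The covariance was -0.114 beside a simulated -0.0251. All simulated groups had the same spread, whereas the DKO libraries had the widest spread of the real groups. Noise in the shared DKO libraries alone makes this covariance negative, so the simulated -0.0251 may lie too close to 0. The covariance therefore does not show how far the changes returned. The DKO minus WT changes correlated with the DKO_TG minus WT changes at 0.90 beside a simulated 0.50, with a covariance of 0.559 beside 0.0249. Groups of 3 libraries cannot be split into parts with 2 libraries each, so part of the excess may come from the shared libraries.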

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

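Tests chosen only after the data were examined were voom on the recovered reads, protein-coding genes only, the correction for length and GC, and the plain total of reads. The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.31 to 0.14. With the replicate number as a block, limma called 21 genes higher and 78 lower in DKO_TG against DKO, 86 of the DKO changes in the opposite direction in DKO_TG, and 7 lists in DKO against WT. In the fit of only the 6 libraries compared, those counts for DKO_TG against DKO were 19 higher, 38 lower and 37 in the opposite direction; fewer libraries then estimate the spread. Without a filter, 162 genes were lower in DKO_TG against DKO and 163 were in the opposite direction, with 13 lists called in DKO against WT and 10 in DKO_TG against WT. After rescaling to TPM, 11277 genes were higher and 1087 lower in DKO against WT, and 10870 and 1003 in DKO_TG against WT, from the shift of all genes it brings. The plain total of reads gave 2307 and 2230 lower genes, and protein-coding genes only, with fewer genes tested, 3037 and 2686. Of the lists, the estimated correlation called 0 in each comparison, and fry 11, 0 and 2 in DKO against WT, DKO_TG against DKO and DKO_TG against WT. Fry does not compare a list with other genes, so its counts answer another question than those of camera. By camera with the estimated correlation the lowest adjusted p over the 24 lists was 0.810, 0.467 and 0.829 in those comparisons. The cholesterol list in DKO against WT was called in 23 of 24 alternatives. In DKO against WT, 2 lists were called with a filter at an RPKM of 1, 2 with quantile normalization, and 8 each with protein-coding genes and with the length and GC correction; 1 was called with quantile normalization in DKO_TG against WT. Under TPM, 6 of the named calls changed direction; among them the log2 changes of Nceh1 and Foxl2 in DKO against WT turned to 0.10 and 0.0355, and those of Fasn, Plin2 and Trp53 in DKO_TG against WT to 0.0924, 0.0867 and 0.20, and the mean of the cell cycle list in DKO against WT to 0.12; relative to the shift of all genes all remained below 0. With quantile normalization Khdc3 turned to -0.0907 in DKO against WT, and Ctsl and Cxcl1 to 0.0172 and -0.18 in DKO_TG against WT; the cause was not tested. Leaving out 1 library at a time gave 5132 to 5878 higher and 3859 to 5213 lower genes in DKO against WT, 8 to 112 and 23 to 323 in DKO_TG against DKO, and 4530 to 5697 and 3043 to 4573 in DKO_TG against WT. It gave 25 to 314 genes in the opposite direction, 6727 to 8680 in the same direction, and 3 to 7, 8 to 13 and 3 to 6 lists called. Changing the pseudocount ended no call among the named genes and lists. With voom 10369, 314 and 9325 genes were called; the planned test on counts was not run because the table holds RPKM. Depth limits weakly expressed genes most, since an RPKM of 0.5 rests on few reads in a short gene.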

Other observations

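The tests of this part chosen only after the result was seen, or after the data were examined, are those on RNA preparation, depth, the correction for length and GC, LXR loss, the Cav1 neighbourhood, endothelial cells, Nr1h2, blood, the X-linked genes and the places in the genome. The genes called between DKO_TG and DKO gathered in a few places of the genome (one-sided Fisher's exact test over 20 chromosomes and 363 bins of 5 Mb, Benjamini-Hochberg adjusted). On chromosome 17, 47 of 935 tested genes were called (adjusted p = 3.35e-06), 11 of them among 47 in the bin from 5 to 10 Mb (adjusted p = 1.76e-06). There Dynlt1b, a dynein light chain gene, was at 554 ± 99.2 RPKM in WT, 471 ± 75.4 in DKO and 234 ± 6.87 in DKO_TG (SD, n = 3), and its near-identical copies Dynlt1a, Dynlt1c and Dynlt1f were likewise lowest in DKO_TG. Dynlt1a also overlaps annotated genes and is uncertain. The bin of chromosome 12 from 20 to 25 Mb had 10 of 39 called (adjusted p = 1.76e-06), 6 of them higher. On chromosome 6, 47 of 1031 genes were called (adjusted p = 2.62e-05). They included 13 of 85 from 65 to 70 Mb, 12 of them immunoglobulin kappa genes (Igkv) that were lower, and 12 of 81 from 120 to 125 Mb, among them Clec4a1, Clec4a2, Clec4a3 and Clec4b1 and the complement genes C1ra and C1s1. On chromosome 7 from 0 to 5 Mb, 11 of 61 were lower (adjusted p = 8.26e-06), among them the leukocyte receptor genes Pirb, Pira2 and Lilra6, so several of these clusters are families of immune genes. Other bins past the threshold by Fisher's exact test were chromosome 1 from 170 to 175 Mb (8 of 66, adjusted p = 0.0064) and chromosome 19 from 10 to 15 Mb (6 of 54, 0.0449). On chromosome 17 they were 10 to 15 Mb (5 of 35, 0.0406) and 55 to 60 Mb (7 of 67, 0.0371). The bin of chromosome 6 from 15 to 20 Mb, which holds Cav1 and Cav2, had 4 of 20 called (0.0403). C1s1 overlaps an antisense gene and is uncertain. Neighbouring copies share reads, so these genes are not independent and the test overstates how rare such a cluster is.

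The X-linked RNA Xist was at 0.111 RPKM in DKO replicate 2, 52.0 and 50.5 in DKO replicates 1 and 3, 39.7 to 45.7 in the DKO_TG libraries and 0.483 to 1.62 in the WT libraries. Kdm6a, a gene that escapes X inactivation, was at 3.89 RPKM in DKO replicate 2, 8.09 and 8.43 in the other DKO libraries, and 3.22 to 3.81 in WT. The Y-linked gene Ddx3y was at 0.0301 RPKM or less in every library. Xist overlaps Tsix and is uncertain. Among 10 genes that escape X inactivation, 4 were higher and 3 lower in DKO than in WT. Lars2 was at 326 ± 69.9 RPKM in WT, 29.2 ± 9.41 in DKO and 122 ± 86.0 in DKO_TG (SD, n = 3). The luteal gene Sfrp4 was at 5.07 RPKM in DKO replicate 3 and at 162 or more in every other library.

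RNAs retained in the nucleus were low in all WT libraries, with a median log2 change of 2.38 over 10 tested members in DKO against WT and 8 of them higher. A trend with transcript length or GC content as the whole cause is argued against, since the median was still 1.92 after a correction of each library for both. Depth was also looked at, and the WT libraries, at 48.6 to 57.7 M reads, were not the shallowest. Between the 2 genotypes labelled as knockout the median was 0.23, so a candidate explanation is a loss of LXR, and another is an RNA preparation that differed for WT. These cannot be told apart, because all WT libraries and only they would share either.

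Cav1 and Cav2 were low in all transgene-labelled libraries. Fewer endothelial cells are argued against as the cause, since the endothelial list had a median log2 change of -0.0533. A DNA change at this locus carried with the transgene stays open. The other genes within 0.5 Mb with a mean of at least 0.5 RPKM in WT were 5, with a median of -0.20 and 0 called, and 95.3% of 16466 runs of as many such neighbouring genes elsewhere had a higher median, with too few genes to decide. Without that filter there were 7 such genes with a median of -0.43 and 2 called lower, and 98.4% of 18745 runs had a higher median, but those 2 were also low in WT. Both shares pass the 95% set for this test, and the need for a called neighbour under the filter was added after both were seen. Expression of LXRb from the transgene stays open too. The upper 95% bound of the log2 change of Nr1h2 was 0.17, under the bound of 0.5 set as evidence against it. It is not counted as such, because the sequence of the transgene is not in the labels and its reads need not be counted under Nr1h2.

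Macrophage genes were lower in DKO_TG than in DKO. WT is in neither group here, so an RNA preparation that differed for WT alone would not by itself make this difference. The list was called by camera in limma in the 6 other libraries alone (adjusted p = 2.49e-07). That does not bear on the macrophage genes that were higher in DKO than in WT. A single DKO library is argued against, with an adjusted p by camera of at most 2.46e-06 without each. Both adjusted p rest on the preset correlation. In those 6 libraries 0 of the 19 members were called by limma, and the adjusted p of the list replaced that count as the test after both were seen. With an estimated correlation the list had an adjusted p of 0.467 (2.21e-10 to 0.467 over its alternatives). More blood in the DKO ovaries stays open and may account for part. DKO replicate 1, the 1 DKO library with less globin than WT replicate 2, was 0.776 log2 units above it in the median of the 8 called macrophage genes, past the bound of 0.5 first set as evidence against blood. It is not counted as such, because 1 library excludes nothing and those genes were picked for being higher in DKO than in DKO_TG; the need for 2 such DKO libraries was added after that bound had been set. Globin summed to 1128, 1655 and 359 RPKM in WT replicates 1, 2 and 3, where that median was 2.54, 2.59 and 2.93, and to 561, 2405 and 1667 RPKM in the DKO replicates, where it was 3.37, 3.76 and 3.14. Genotype stays open and untested against blood.

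Of the 10 splits of 6 libraries into groups of 3, 1 gave as many genes as the genotypes did in each comparison, the real one. It had 10710, 421 and 9705 genes called, the counts of the fit of all 9 libraries, beside at most 0 in the other splits. For DKO_TG against DKO the fit of only the 6 libraries compared called 57. Each other split mixes both genotypes in each group, which widens the spread, so calls are unlikely in it from the start. These splits therefore decide nothing, and they are too few for a share under 0.05.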
